A study of Homo sapiens with 6 samples.

How the data were processed

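Total RNA from 3 cultures of NGP CRISPR control cells and 3 of NGP ALK(LF655del) cells, grown with 10% fetal bovine serum, was spiked with the ERCC mix of synthetic transcripts, labelled from 100 ng by 3' in vitro transcription and hybridised to PrimeView arrays, per the labels' protocols. The values are the authors' processed values, 1 intensity per probe set and array on a linear scale. MAS5, R 3.1.3 and the affy package are named in the submitters' processing notes, with no role or order; how probe sets were summarised and scaled is not given in the sources used here. Of 100 ERCC probe sets, 41 reached the filter level given below and were used for the spike-in level. In the deposited intensity values these lie at nearly the same level on every array (mean log2 9.32 ± 0.01 in control and 9.30 ± 0.04 in edited arrays, SD, n = 3), while the medians of the genes tested differ. The scale of the deposited values is thus close to one set by the spike-ins. The hybridisation controls, bacterial and phage transcripts that are not from the cells (9 probe sets), averaged 10.77 ± 0.14 and 11.00 ± 0.50. The log2 ratio of the 3' to the 5' probe set of ACTB, a sign of RNA quality, was 0.58 ± 0.03 in control and 0.47 ± 0.05 in edited arrays (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow), and that of GAPDH was -0.05 ± 0.04 and -0.06 ± 0.05 (p = 0.7, same exact test).

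Of 49495 probe sets, 202 were controls. Of the other 49293, the platform annotation gave 1 gene symbol for 45278, several for 1333 and none for 2682; only the first kind was used for genes. Symbols were updated through gene identifiers to the RefSeq annotation of GRCh38.p14, in which 45208 of these probe sets were found, and 0 symbols changed. That annotation also gave which genes neighbour each other; the build behind the array annotation is not given in the sources used here. Values were taken as log2 of the deposited intensity with no further scaling and no pseudocount. A probe set entered if its mean log2 over the 6 arrays was at or above the 40th percentile, a level of 5.75 (an intensity of 53.6), which 27167 passed. Each gene was represented by its brightest probe set over all arrays, giving 12138 genes; 7134 had over 1 probe set above the filter. On 1602 genes that probe set was of the kind that can also bind related transcripts.

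Edited and control arrays were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend, two-sided, and Benjamini-Hochberg adjustment at 0.05. On the values as deposited the prior degrees of freedom of eBayes were infinite. Each SE and p on that scale thus comes from the intensity trend over all genes, not from the gene's own replicates. Lists of genes (36, written before the data were examined) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over the 36 lists. The relative scale shifted every array to a common median over the genes tested. Named genes were ALK, MMP9, CTNNB1 and MYCN; the 12 largest rises and 12 largest falls among genes past the test whose groups of arrays did not overlap; up to 4 passing members per list; for 6 lists closest to the question, the 2 largest changes where no member passed; and the brightest 2 markers of each other cell type with any that passed. The test, lists, rule for named genes and most alternatives were fixed before the data were examined; choosing members by the relative scale as well was decided afterwards. The settings varied were median, quantile and ERCC scaling, no filter or the 60th percentile, the mean of a gene's probe sets or every probe set on its own, no trend, robust eBayes, pseudocounts of 16 and 64, a replicate block, and leaving out each array. ERCC scaling aligned the median of all 100 ERCC probe sets, dim ones included, so it differs from the spike-in level above. As only 41 of the 100 reached the filter level, that median itself rests on dim probe sets.

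The tests were tried on simulated data built from the gene levels, array shifts and residual spread of the edited and control arrays, with 200 of 12138 genes changed. As deposited, 0% of the genes changed by 0.5 on the log2 scale, 10% of those changed by 1 and 100% of those changed by 2 or 3 were recovered, and 0 unchanged genes were called. Relative to the array median these were 64%, 90% and 100%, with 5 unchanged genes called. A strongest run of neighbouring genes was searched on each autosome on the relative scale, over runs of at least 40 genes, and set against 1000 shuffles of the gene order and 1000 shuffles within 20 bins of brightness. It was repeated on every other gene of each chromosome to measure the genes left out. This search and its tests were added after the data were seen. The last 2 replaced draws of genes of equal brightness without a search, and the share of genes of the found regions that shifted their way (75% and 83.4%), which the search itself sets and by which a copy number difference had first been counted as fitting. Its first scoring, against the rest of the same chromosome, picked the unshifted part of chromosomes 1 and 17 and was replaced by scoring against the median of all genes.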

Results

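Gene expression was measured in NGP cells, an established human neuroblastoma line, on 6 PrimeView arrays, which read the 3' part of transcripts. There were 3 arrays of CRISPR control cells and 3 of CRISPR-edited cells that the labels call ALK(LF655del), a small in-frame deletion in the part of the receptor tyrosine kinase ALK outside the cell. None of the cells were treated with a compound. Per the labels' protocols the replicates were separate biological samples, and 100 ng of total RNA was labelled for each array. The comparison of edited with control cells asks what the deletion, which lies where ALK can be cut at the cell surface, changes in the transcriptome. Precision is limited by the number of arrays. Apart from the replicate number, the titles of the edited arrays give the same name. Whether the edited cells are a single clone is not given in the sources used here. Replicates of the same edited cells cannot separate the deletion from other differences between these cells and the control cells. That limit holds for every gene and list below.

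ALK itself was read at a log2 intensity of 7.47, 7.68 and 7.58 in the control replicates and 6.82, 8.05 and 8.01 in the edited replicates. The difference of 0.05 ± 0.41 (SE, n = 3 per group; limma adjusted p = 0.977) was smaller than the spread between replicates, and relative to the array median it was -0.24 ± 0.14 (limma adjusted p = 0.26). A 3' array need not see a short coding deletion, so this value does not check the genotype.

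The edited cells had higher transcripts of the transcription factors NPAS4, EGR3 and EGR4 and lower transcripts of S100A11, PRAME, DBH, NGFR and COL3A1. The fall of NGFR is less certain, since it did not pass when its probe sets were averaged. NPAS4, a transcription factor induced by neuronal activity, rose 17.9-fold, and EGR3 and EGR4, zinc finger factors of the early growth response family, rose 9.83-fold and 6.67-fold. S100A11, a calcium-binding protein, and PRAME, a tumour antigen, fell to levels 16.6-fold and 16.2-fold below those of the control cells. DBH, the enzyme that makes noradrenaline from dopamine, fell 5.95-fold. All these folds are on the values as deposited. With each array shifted to a common median, rises were smaller and falls larger. NPAS4 then rose 14.7-fold and EGR3 8.08-fold, and S100A11 changed by -4.33 on the log2 scale. NPAS4 and EGR4 in control cells and S100A11 and PRAME in edited cells lay below 5.75, the log2 level under which a probe set counted as dim, so the sizes of these 4 folds are uncertain. The 2 groups of arrays also differed in the ACTB 3' to 5' ratio given below.

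On the values as deposited, 65 of 12138 genes passed the test, 42 of them higher and 23 lower in the edited cells, all with an absolute log2 change of at least 1. The SE and p of each gene on this scale came from the intensity trend over all genes (median SE 0.38), so smaller changes could hardly pass. The arrays differed in their level as a whole. The median log2 intensity of the genes tested was 7.51, 7.73 and 7.41 in the control replicates and 7.28, 8.41 and 7.81 in the edited replicates, and the median log2 change over all genes was 0.25. The group means of these medians, 7.55 ± 0.17 and 7.83 ± 0.56 (SD, n = 3), did not differ by more than the replicates did (two-sided exact permutation p = 0.6; the smallest p that 3 against 3 arrays allow is 0.1). The log2 ratio of the 3' to the 5' probe set of ACTB, a sign of RNA quality, separated the groups, with 0.55 to 0.61 in control and 0.43 to 0.52 in edited arrays (two-sided exact permutation p = 0.1). The same ratio of GAPDH did not, with means of -0.05 and -0.06 (two-sided exact permutation p = 0.7). With each array shifted to a common median, 2425 genes passed, 1203 higher and 1222 lower, and 131 of them changed by an absolute log2 value of at least 1. All 65 genes were among these and in the same direction. Changes on this second scale are called relative to the array median below.

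**Figure D1:**
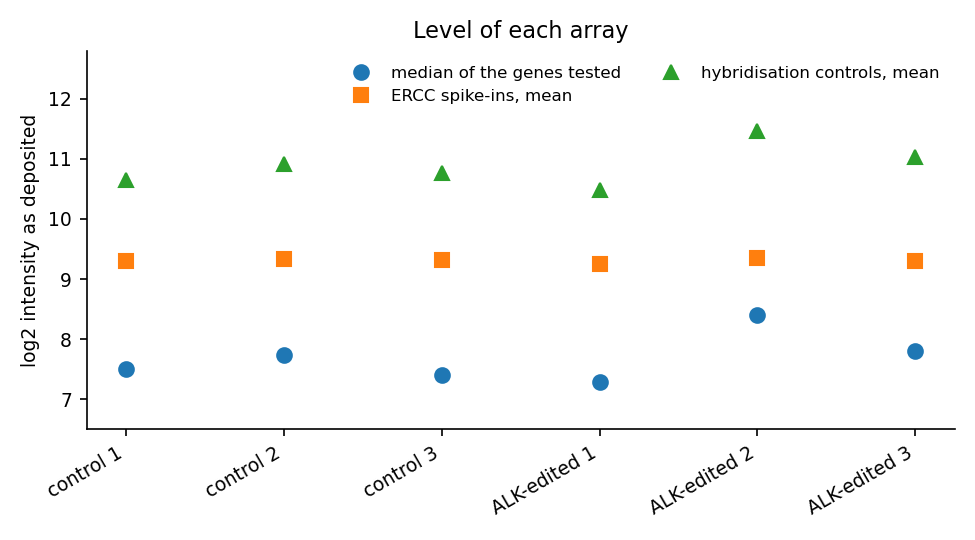
Level of each of the 6 arrays on the log2 intensity scale as deposited. Circles give the median of the genes tested, squares the mean of the 41 ERCC probe sets above the filter level and triangles the mean of the hybridisation controls. The spike-in means lie between 9.26 and 9.34 on all arrays, while the medians run from 7.28 to 8.41.

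Among the 12 largest rises, NPAS4 went from 5.29 ± 0.16 to 9.45 ± 0.55 on the log2 scale (SD, n = 3; limma adjusted p = 2.95e-21). EGR3 went from 6.08 ± 0.13 to 9.38 ± 0.57 and EGR4 from 5.63 ± 0.04 to 8.36 ± 0.40. FOS, a subunit of the AP-1 transcription factor, rose by a log2 change of 2.27 ± 0.34 (SE; limma adjusted p = 2.8e-08). DUSP5, a phosphatase that inactivates nuclear ERK, rose by 2.10 ± 0.34. TTC9B rose by 2.56 ± 0.35 and CELF5, a neuronal RNA-binding protein, by 2.53 ± 0.42. ID4, an inhibitor of helix-loop-helix transcription factors, rose by 2.30 ± 0.41, and STMN4, a neuronal regulator of microtubules, by 2.29 ± 0.38. MAMLD1 rose by 2.26 ± 0.33, FGF13 by 2.22 ± 0.40 and TCEAL7 by 1.94 ± 0.41 (limma adjusted p = 0.00112, the highest of the 12). In control cells NPAS4, EGR4, MAMLD1 and DUSP5 lay below the dim level of 5.75, so their folds rest on little control signal. By the rule that chose them, each of the 12 genes was higher in all 3 edited arrays than in all 3 control arrays.

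Among the 12 largest falls, S100A11 went from 9.29 ± 0.15 to 5.24 ± 0.27 (SD, n = 3; limma adjusted p = 6.34e-21) and PRAME from 9.28 ± 0.11 to 5.26 ± 0.48. In edited cells S100A11, PRAME, RNF182, AMPH, COL3A1 and THSD7B lay below the dim level, so the sizes of these 6 falls rest on little edited signal. DBH went from 8.89 ± 0.09 to 6.32 ± 0.53. NGFR, the low-affinity neurotrophin receptor, changed by -2.52 ± 0.42 (SE; limma adjusted p = 1.43e-06), and COL3A1, a fibrillar collagen chain, by -2.40 ± 0.34. RNF182, a ubiquitin ligase, changed by -2.44 ± 0.28 and GNB4, a G protein beta subunit, by -2.29 ± 0.38. USP18, a protease that removes ISG15 from proteins, changed by -2.09 ± 0.40. THSD7B changed by -2.06 ± 0.35, AMPH, a synaptic vesicle protein, by -1.96 ± 0.30, SLC38A5, an amino acid transporter, by -1.95 ± 0.36, and TMEM98 by -1.94 ± 0.38 (limma adjusted p = 0.00024, the highest of the 12). NGFR and TMEM98 lie in a part of chromosome 17 whose genes had a median change of -0.26 relative to the array median. The fall of NGFR did not pass the test when its probe sets were averaged.

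**Figure D2:**
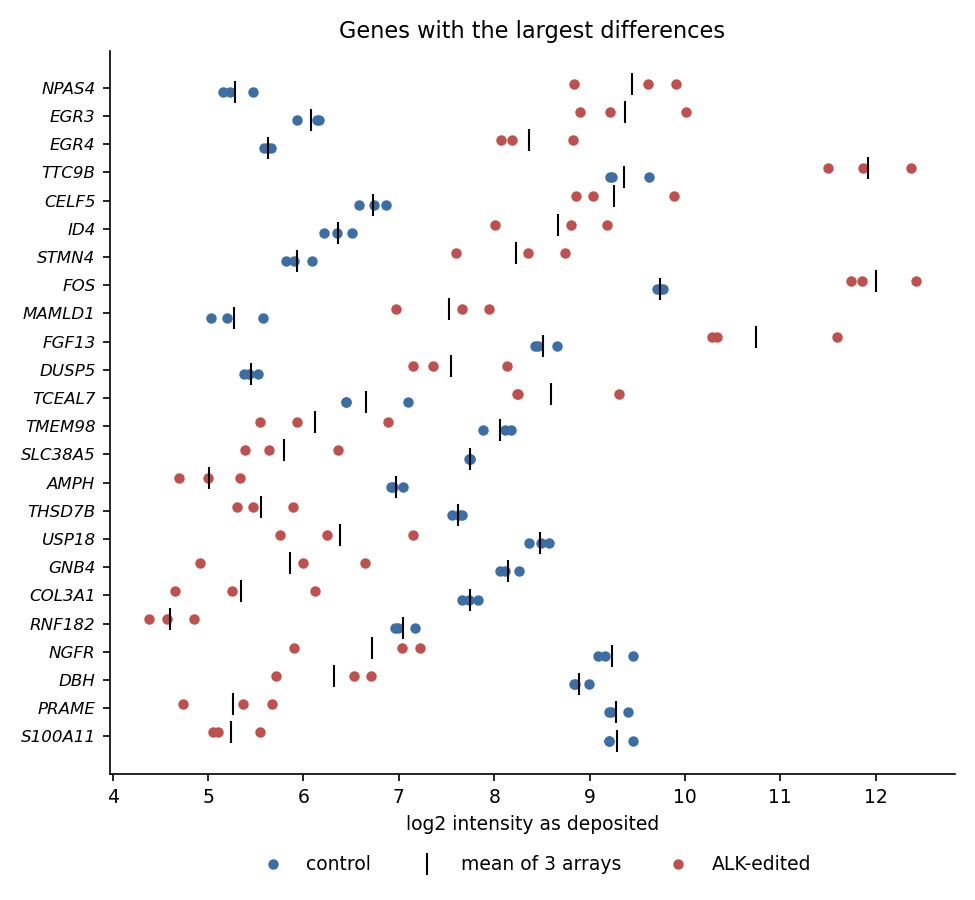
The 12 genes with the largest rise and the 12 with the largest fall among those past the test whose groups of arrays do not overlap, on the log2 intensity scale as deposited. Each point is 1 array, blue for control and red for ALK-edited cells, and the black ticks are means of 3 arrays. The lack of overlap between the groups follows from the choice of genes.

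Immediate early genes, which cells transcribe within minutes of a stimulus, were higher as a group. Of 21 measured members, 7 rose and 0 fell, and 16 rose relative to the array median. Adjusted over the list alone, 16 also rose and 1 fell on that scale. Besides EGR3, EGR4 and FOS, ATF3 rose by a log2 change of 1.72 ± 0.42 (limma adjusted p = 0.0135), but it did not pass with ERCC medians aligned. Here and below, that setting rests on dim spike-in probe sets, so a call lost in it is hard to interpret. ATF3 lies in a part of chromosome 1 whose genes had a median change of 0.24 relative to the array median. The list's median change was 1.08, and 0.80 relative to the array median (camera with a preset correlation, adjusted p = 6.48e-31 and 1.44e-13). The call was lost with an estimated correlation (adjusted p = 0.682, and 0.913 relative to the array median). Camera with an estimated correlation called 0 of the 36 lists on either scale (lowest adjusted p = 0.321 as deposited and 0.913 relative to the array median). After adjustment it thus set no list apart from the others. The correlation estimated for the immediate early list was 0.86 as deposited and 0.39 relative to the array median, against the preset 0.01. The p with the preset correlation does not allow for genes that move together this strongly, so it overstates the evidence. The edited arrays, in which the immediate early genes were higher, are also those with the lower ACTB ratio given above, and the 2 cannot be separated with these arrays. The same holds for the other lists called below.

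**Figure D3:**
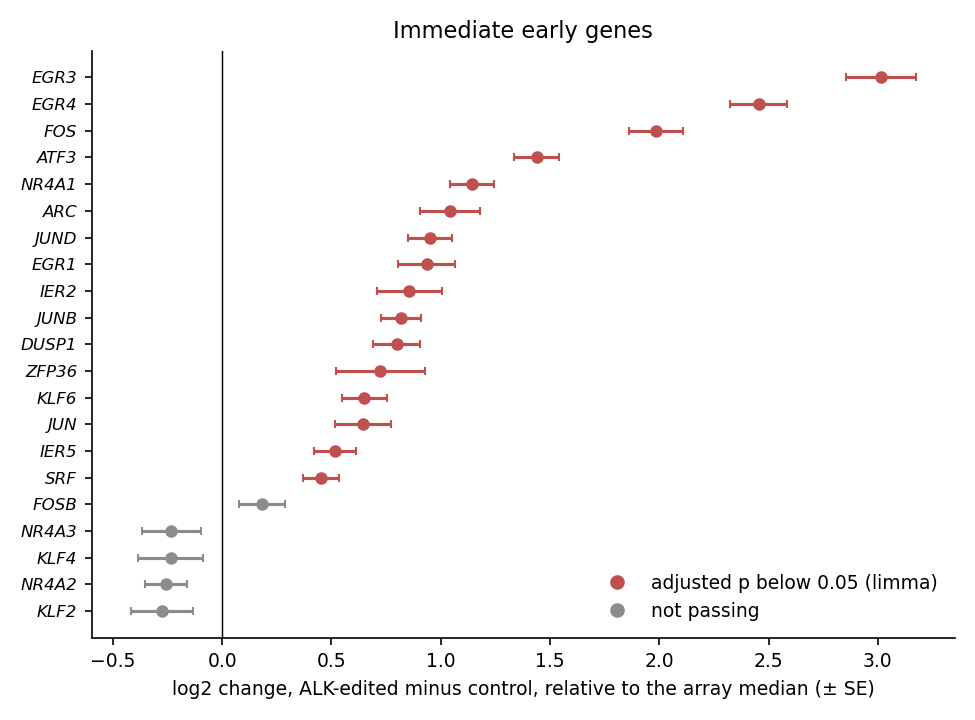
Log2 change of the 21 immediate early genes measured, ALK-edited minus control, relative to the array median, with bars of 1 SE. Red points passed the limma test and grey points did not; 16 of the 21 genes passed, all of them higher.

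Genes of ERK feedback and output were mixed. Of 26 measured, 6 rose and 3 fell relative to the array median; DUSP5 and VGF, a secreted neuropeptide precursor (log2 change 0.70 ± 0.09), were among the former, and ELK3, an ETS factor, at -1.78 ± 0.12, and SPHK1 at -0.53 ± 0.11 among the latter. ELK3 also fell on the values as deposited, by 1.50 on the log2 scale. The list was not called (camera adjusted p = 0.317 as deposited and 0.475 relative to the array median). SPHK1 lies in the same part of chromosome 17 as NGFR.

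Mesenchymal genes were not called as a list (camera adjusted p = 0.944; 1 of 23 rose and 0 fell as deposited). With every probe set tested on its own, so that a gene can count more than once, the list was called lower (adjusted p = 9.26e-06). Thrombospondin THBS1 rose by 1.39 ± 0.36, but it did not pass with ERCC medians aligned. When set against the array median, THBS1 and the smooth muscle actin ACTA2 (0.85 ± 0.14) rose, whereas 4 members fell, among them fibronectin FN1 (-1.40 ± 0.25) and cadherin CDH11 (-0.83 ± 0.10). Of 27 genes for collagens, laminins and other matrix, 3 rose and 4 fell relative to the array median. In that list the proteoglycan agrin, AGRN, rose by 1.74 ± 0.41 as deposited, but its 1 other probe set went the other way, so its change is uncertain.

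Of 20 Wnt and beta-catenin targets, TNFRSF19 rose, by 1.50 ± 0.37, and no other member passed as deposited (camera adjusted p = 0.16 for the list, and 0.000485, higher, with every probe set on its own). TNFRSF19 did not pass with the mean of probe sets or with ERCC medians aligned. On the relative scale FZD7, a Wnt receptor (0.48 ± 0.14), and LEF1, a partner of beta-catenin (0.34 ± 0.09), rose too, and the Notch ligand JAG1 fell (-0.68 ± 0.13). CTNNB1, which encodes beta-catenin, differed by 0.33 ± 0.32 (limma adjusted p = 0.915), and by 0.05 ± 0.11 relative to the array median. MYCN, the oncogene amplified in many neuroblastomas, differed by 0.05 ± 0.20 (limma adjusted p = 0.949), and by -0.23 ± 0.19 relative to the array median.

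No metalloprotease or inhibitor among 24 measured passed as deposited (limma; camera adjusted p = 0.834 for the list). Relative to the array median, 8 rose and 4 fell. The inhibitor TIMP3 (-1.22 ± 0.19), the matrix protease ADAMTS9 (-1.01 ± 0.12) and the membrane-anchored protease ADAM9 (-0.59 ± 0.17) fell, and ADAMTS1 rose (0.67 ± 0.11). ADAM9 did not pass after quantile normalization (limma adjusted p = 0.0736). TIMP3 ended below the dim level, at 5.40. MMP9, a secreted gelatinase, was too dim to be tested, at a log2 intensity of 5.41 ± 0.25 in control and 5.54 ± 0.39 in edited cells (SD, n = 3).

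The factors that mark the adrenergic and the mesenchymal state of neuroblastoma cells were not called as lists (camera adjusted p = 0.835 and 0.944). No adrenergic factor passed as deposited; the 2 largest differences were 1.00 ± 0.37 for SIX3 and 0.64 ± 0.26 for GATA3. On the relative scale SIX3 rose (0.72 ± 0.10), and KLF7 (-0.88 ± 0.09) and DACH1 (-0.63 ± 0.14) fell. Of the mesenchymal-state list EGR3 rose on both scales, and FN1, SIX4 (-1.19 ± 0.18, to a dim level of 5.69) and CREG1 (-0.81 ± 0.08) were among 4 of 22 that fell relative to the array median. Of 17 catecholamine and chromaffin genes, DBH, the granule protein CHGB (-1.17 ± 0.09) and GCH1, which makes a cofactor of tyrosine hydroxylase (-0.92 ± 0.16), were among 5 that fell relative to the array median, and the neuropeptide NPY (0.89 ± 0.21) was among 3 that rose.

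No member of the mitosis or DNA replication lists passed as deposited, but both lists were called higher (camera adjusted p = 0.00459 and 0.00508). With an estimated correlation neither call held (adjusted p = 0.988 for both). As deposited, the call of the mitosis list was also lost without control replicate 3 (camera adjusted p = 0.0733) and without edited replicate 2 (0.0714). Relative to the array median both lists were called (camera adjusted p = 0.00032 and 0.000434), also with any array left out. An estimated correlation lost both calls there too (camera adjusted p = 0.913 and 0.957). Of 30 mitosis genes, 8 rose relative to the array median, with the kinase PLK1 at 0.39 ± 0.08. Of 36 DNA replication genes, 11 rose and 1 fell, with the ligase LIG1 at 0.60 ± 0.09, E2F2 at 0.59 ± 0.09 and the thymidylate synthase TYMS at 0.45 ± 0.11. CENPF (0.46 ± 0.12) and NEK2 (0.40 ± 0.10) of the mitosis list lie in the part of chromosome 1 that holds ATF3. Of 29 MYC and MYCN targets, none passed on either scale (limma).

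Of the other lists, cancer-testis genes were called lower (camera adjusted p = 4.59e-14; adjusted p = 0.321 with an estimated correlation and 0.171 after quantile normalization), with 4 measured members and PRAME alone past the test as deposited. On the relative scale genes of the ATF4 and unfolded protein response were lower (camera adjusted p = 0.036; 6 of 28 fell and 2 rose; adjusted p = 0.957 with an estimated correlation) and HOX genes higher (camera adjusted p = 0.036; 4 of 13 rose; adjusted p = 0.957 with an estimated correlation and 0.0812 after quantile normalization). Of the ATF4 list 14 genes fell and 3 rose after quantile normalization (camera adjusted p = 0.00137). As deposited 0 fell and 1 rose, and that list was not called (camera adjusted p = 0.371). Relative to the array median, the ATF4 call was lost without control replicate 2 (adjusted p = 0.105), edited replicate 2 (0.093) and edited replicate 3 (0.114), and the HOX call without control replicate 1 (0.0883), edited replicate 2 (0.0621) and edited replicate 3 (0.0593). HOXC6 rose by 0.82 ± 0.11 and HOXD11 by 0.58 ± 0.09 on that scale, and SESN2, a stress-induced regulator of mTORC1, fell (-0.72 ± 0.11). Single members passed as deposited in several lists that were not called. The neuronal glycolytic enzyme ENO2 rose by 1.75 ± 0.39, the prolyl hydroxylase P4HA2 changed by -1.29 ± 0.28, the matricellular protein CCN1 rose by 1.55 ± 0.42 and the retinaldehyde dehydrogenase ALDH1A3 changed by -1.71 ± 0.28. P4HA2 and ALDH1A3 ended below the dim level, at 5.12 and 4.98, and CCN1 did not pass with ERCC medians aligned. Among 18 genes for ALK ligands and signalling partners, 2 rose and 4 fell relative to the array median; STAT3 (-1.20 ± 0.11) and the adaptor GRB2 (-0.35 ± 0.10) both lie in the part of chromosome 17 named above.

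Neighbouring genes shifted together along several chromosomes, a feature singled out after the values were seen, and the 2 strongest runs by the score of the search lay on chromosomes 1 and 17. From CACYBP to PGBD2, the last gene tested there, 280 genes of chromosome 1 had a median change of 0.24 relative to the array median, and 505 genes of chromosome 17 from LINC02693 to NPTX1 had a median of -0.26. On the values as deposited these medians were 0.53 and 0.02, beside the median of 0.25 over all genes, so the sign for chromosome 17 depends on the scale. Shorter runs on other chromosomes shifted by somewhat less relative to the array median, with medians of -0.23 for 80 genes from PSMD6 to NDUFB4 on chromosome 3 and -0.22 for 70 genes from ZFAND1 to SYBU on chromosome 8.

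**Figure D4:**
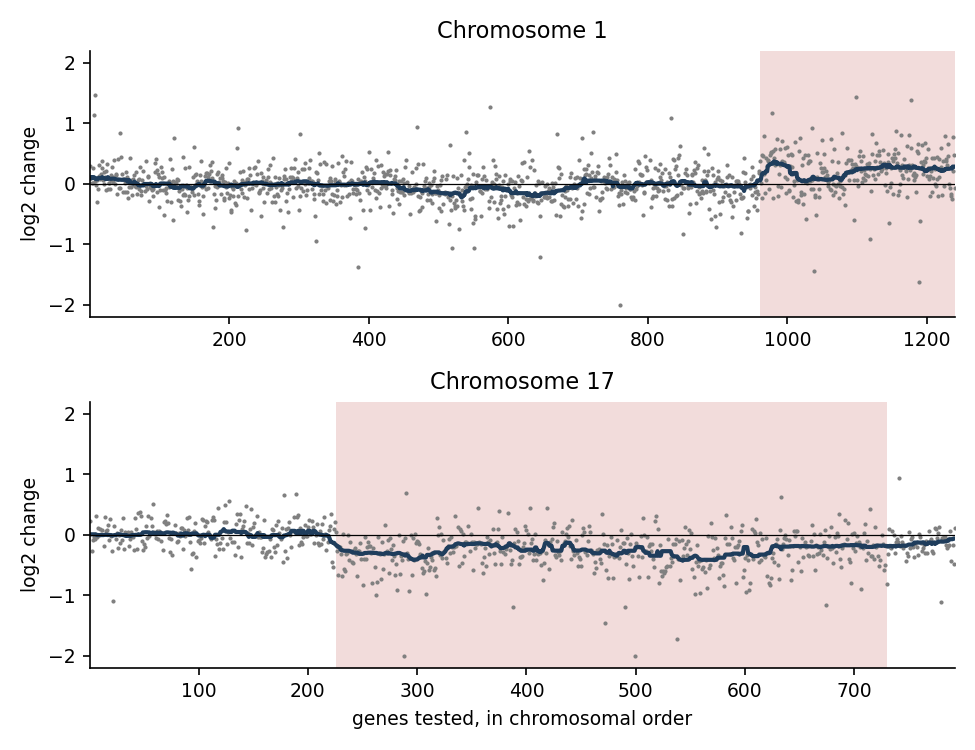
Log2 change of each gene tested, ALK-edited minus control, relative to the array median, in the order of the genes along chromosomes 1 and 17 (horizontal axis: position in that order; points beyond 2 are drawn at 2). The line is the running median of 41 genes and the shading marks the regions from CACYBP to PGBD2 and from LINC02693 to NPTX1, with medians of 0.24 and -0.26.

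Markers of other cell types did not move together. Of 5 fibroblast markers above the filter, 1 rose relative to the array median (THY1, 0.59 ± 0.10) and 2 fell (COL3A1, and COL1A1 at -0.69 ± 0.14, which lies on chromosome 17 as above). Of 5 endothelial, 4 leukocyte and 4 epithelial markers above the filter, none passed on either scale (limma); the brightest of each type were VWF and TIE1, CD79A and TYROBP, and CLDN4 and MUC1, at mean log2 intensities between 6.55 (TIE1) and 7.78 (MUC1) in edited cells. TYRP1 of the melanocyte list (-0.60 ± 0.18) and LIN28B (-0.49 ± 0.12) fell, and WT1 (0.35 ± 0.10) rose, relative to the array median; TYRP1 did not pass after quantile normalization (limma adjusted p = 0.0663).

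The count on the values as deposited moved by more than 1.5 times with any single array left out: 25, 26 and 24 genes without control replicate 1, 2 and 3, and 1568, 234 and 20 without edited replicate 1, 2 and 3. Relative to the array median it stayed between 1774 and 2319.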

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

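The tests of array scaling and the splits of the arrays were chosen after the results were seen. Probe sets with several gene symbols or none were kept out of the gene comparison. When tested in the same way, 210 of 2172 above the filter were higher and 176 lower in the edited cells relative to the array median (limma), and 23 passed as deposited. Those with no symbol made up 143 of the higher and 112 of the lower ones. Groups of 3 arrays were not searched for single deviating arrays.

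Few genes passed as deposited (65) and many relative to the array median (2425). Taking the array medians off left 28.4% of the spread of the hybridisation controls over the 6 arrays, which are not transcripts of the cells, so 1 scaling factor per array may carry most of the spread. More RNA per edited cell could add to the factors, but the exact permutation p of the array medians between groups was 0.6 in a design that cannot go below 0.1, so this cannot be told apart from scaling. Of the 10 splits of the 6 arrays into 3 and 3, the real one gave 65 and 2425 genes and the highest of the others 20 and 0, with 1 split, the real one, reaching each count; 10 splits are too few for a share under 0.05.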

How the results depend on the processing

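Fits on the relative scale that combine 2 choices, and those without the 2 chromosome regions, were chosen after seeing the data; an array-weighted fit also added then did not converge and gives no value. The cause of the changes below was not tested unless stated. Of the 65 genes changed as deposited (42 higher, 23 lower), all were also called after array medians were aligned and after quantile normalization, where 2425 (1203 higher, 1222 lower, 131 by at least 1 on the log2 scale) and 2859 (1438, 1421 and 123) genes changed. The share of higher calls was 64.6% as deposited, 49.6% relative to the array median and 50.3% after quantile normalization. Aligning the ERCC medians gave 41 genes, 21 of them higher, and all 41 changed by at least 1. Those medians rest on dim spike-in probe sets, so losses and changes of sign in this setting are hard to interpret. No filter gave 130 (65 higher, 65 lower, 98 by at least 1), and the 60th percentile, with fewer genes tested, 39 (11 lower, 39 by at least 1). Every probe set on its own gave 104 (76 higher, 104 by at least 1), and no values for single genes. Without a trend 68 genes were higher, and with a pseudocount of 64, 43 changed by at least 1. With the replicate number as a block there were 120 (84 higher, 36 lower, 108 by at least 1) and 2491 relative to the array median. Same-numbered arrays did not deviate together (correlations of -0.10, -0.09 and 0.14), and differently numbered ones ranged from -0.24 to 0.31. These values give no sign of a pairing by number, but 3 arrays per group are too few to exclude one. Leaving out 1 array gave 20 to 1568 genes, 11 to 1530 higher, 9 to 135 lower and 20 to 572 by at least 1; without edited replicate 1 or 2 the 65 genes were all kept. Relative to the array median, the count stayed within 1.5 times of 2425 in all settings tried, but without a filter 766 genes were lower. Of 40 named genes, 13 lost their call without at least 1 array, among them TCEAL7, USP18, SLC38A5, TMEM98, NGFR, ENO2 and ELK3. AGRN and TNFRSF19 were lost with the mean of probe sets, and THBS1, CCN1, ATF3 and TNFRSF19 with ERCC medians aligned. ALK changed sign to -0.24 with array medians aligned, -0.23 after quantile normalization and -0.015 with ERCC medians aligned, and ranged from -0.17 to 0.45 with an array left out; MYCN changed to -0.23, -0.071 and -0.012, and ranged from -0.10 to 0.14. The immediate early list kept its call in all settings but the estimated correlation and fry as deposited (adjusted p = 0.299; 0.0431 relative to the array median, and 0.0208 as deposited for changes in either direction). DNA replication kept its call in all but the estimated correlation and fry on both scales (fry adjusted p = 0.758, and 0.105 relative to the array median). With every probe set on its own the mesenchymal list (adjusted p = 9.26e-06, lower) and the Wnt list (0.000485, higher) were called; probe sets of 1 gene count repeatedly there. The other lists that changed direction were called in neither setting, with camera adjusted p as follows. With array medians aligned: adrenergic factors 0.909, MYC targets 0.712, Notch 0.848 and oxidative phosphorylation 0.662. After quantile normalization: integrins 0.986, adrenergic factors 0.965, mesenchymal-state factors 0.982, neural crest 0.965, MYC targets 0.323, hypoxia 0.965, sterol synthesis 0.982, Notch 0.781 and oxidative phosphorylation 0.357. With ERCC medians aligned: MYC targets and oxidative phosphorylation 0.931. With no filter: mesenchymal 0.704, integrins and hypoxia 0.723, mesenchymal-state factors 0.819, axon guidance and amplicon genes 0.846, Notch 0.716, NF-kB 0.367, ribosomal proteins 0.943 and ALK partners 0.546. With the 60th percentile: matrix and sterol synthesis 0.994, mesenchymal-state factors 0.128, ERK genes and MYC targets 0.876, hypoxia 0.52 and oxidative phosphorylation 0.894. With every probe set: axon guidance 0.326, MYC targets 0.486, hypoxia 0.312 and oxidative phosphorylation 0.597. With the mean of probe sets: mesenchymal-state factors, axon guidance, MYC targets and Notch 0.969 and oxidative phosphorylation 0.905. Without the 2 regions: mesenchymal-state factors and axon guidance 0.856, neural crest 0.437 and ALK partners 0.905. With an array left out the range was 0.788 to 0.999 for mesenchymal genes and axon guidance, 0.659 to 0.999 for mesenchymal-state factors, 0.835 to 0.999 for MYC targets, 0.716 to 0.999 for sterol synthesis, NF-kB and oxidative phosphorylation, and 0.732 to 0.999 for Notch. Genes near the filter level of 5.75 have the least signal over background.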

Other observations

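The search for runs of neighbouring genes with all its tests and the test of heat shock genes were chosen after the results were seen. Single members of further lists passed relative to the array median, but camera called none of these lists as shifted in 1 direction. Of 21 p53 targets, 6 fell, among them the cell cycle inhibitor CDKN1A (-0.78 ± 0.11), and 3 rose, among them TP53I3 (0.63 ± 0.12). Of 30 neuronal differentiation genes, 8 rose, with the growth cone protein GAP43 at 0.45 ± 0.12, and the neurofilament gene NEFL fell (-0.40 ± 0.09). In the TGF-beta and BMP list ID3 (0.92 ± 0.16) rose with ID4, and INHBE (-1.60 ± 0.21) and LTBP1 (-1.07 ± 0.12) fell. In the Notch list HES4 rose (1.14 ± 0.09) and the glycosyltransferase MFNG fell (-1.69 ± 0.20). Of 30 ribosomal protein genes and 12 antigen presentation genes, none passed on either scale (limma). Of 18 interferon-stimulated genes USP18 alone passed on either scale.

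The 2 strongest runs of genes next to each other lay on chromosomes 1 and 17, and the deletion and the history of the edited cells cannot be separated here. On chromosome 1, 280 genes from CACYBP to PGBD2 had a median change of 0.24 relative to the array median (112 rose and 8 fell), against -0.03 for the rest of that chromosome; on chromosome 17, 505 genes from LINC02693 to NPTX1 had a median of -0.26 (10 rose and 210 fell), against -0.02. Of 1000 shuffles of the gene order 0 gave a run as strong, as did 0 of 1000 shuffles among genes of the same brightness, which argues against a chance run and against brightness; shuffling does not allow for neighbours that are regulated together, and 11 of 20 other autosomes also held a run with a shuffle p under 0.05, with medians between -0.23 (80 genes of chromosome 3) and 0.10. With the runs found on every other gene, 72.7% and 84.3% of the genes left out of the search shifted the way of their run on chromosomes 1 and 17, against up to 79.5% for downward runs (chromosome 13) and 65.8% for upward runs (chromosome 9) of other autosomes. The medians of these genes were 0.21 and -0.20, further from 0 than on any other autosome (-0.14 on chromosomes 4 and 8), but a difference in chromosome copy number between the edited and the control cells cannot be told from neighbours regulated together, and no DNA was measured.

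The regions held 340 of the 2425 genes that changed relative to the array median (14%, with 6.47% of the genes tested) and 6 of the 65 as deposited. Without them 2029 genes changed relative to the array median and 57 as deposited.

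Immediate early genes were called higher in the edited cells with a preset correlation, but not with an estimated one (camera adjusted p = 0.682, and 0.913 relative to the array median). With an estimated correlation 0 of the 36 lists were called on either scale. The median of the immediate early list lay at 0.67 or more above the control mean in each edited array, against at most 0.15 in a control array. No single array thus carried the rise. Stress during handling could raise these genes, but the 17 heat shock genes had a median change of -0.0695 relative to the array median, with 0 up and 2 down, which argues against stress that includes a heat shock response. More output of the ERK pathway may play a part. The 26 ERK genes measured had a median change of 0.12, above that of random lists (permutation p = 0.0033, which does not allow for genes that move together). The ERK list shares no member with the immediate early list, so nothing was removed from it. It may still hold genes that respond as early, so its shift is not separate evidence. Of the ERK genes 3 fell relative to the array median and camera did not call the list on that scale (adjusted p = 0.475), so this stays open. The time from the last change of medium to harvest was not tested, nor was RNA quality, although the ACTB 3' to 5' ratio separated the groups. The GAPDH ratio did not separate them.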
